A study of Mus musculus with 40 samples.

How the data were processed

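The measurements were RNA sequencing profiles of 4T1 cells, a mouse mammary carcinoma line, each carrying 1 of 10 short hairpin RNAs. A short hairpin RNA (shRNA) is a transcribed stem-loop that the cell processes into a small RNA, which then lowers mRNAs that pair with it. Per the labels' protocols, cells were infected at a multiplicity of 0.3 and selected for about 10 days, with 1 µg/ml puromycin for hairpins 66708 and 88943 and 500 µg/ml hygromycin for the other 8. RNA was purified with DNase treatment, 100 ng was amplified with the NuGEN Ovation RNA-Seq V2 system, the cDNA was sheared to a target of 200 bp, and 76 bp reads were sequenced, per the labels' protocols. No untransduced line and no hairpin against an unrelated gene was among the samples analysed here.

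Groups were taken from the sample titles and the drug of selection. Each of the 10 hairpins belonged to the table its samples are assigned to, 5 to the Slpi table and 5 to the Mgp table. The source of each hairpin was inferred and not read from a label: 66708 and 88943 carry catalogue-style numbers and puromycin selection and were treated as the hairpins of the TRC collection, and the 8 hairpins with gene-based names as shERWOOD designs. Source, vector and selection drug therefore coincide in every comparison. The labels list 40 samples, 4 per hairpin with a letter and a number each, while the tables hold 20 columns, 2 per hairpin, which could not be tied to single samples. Each column was used as 1 replicate of its hairpin, n = 2. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

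The authors' deposited values are on a log2-like scale after variance stabilization, and the submitters' processing notes name alignment to mm10 with Bowtie2, counting with HTSeq and DESeq, without versions. The annotation used for counting, the strand setting and other parameters are not given in the sources used here. In each table the smallest value is shared by all genes without reads, 7.92 in the Slpi table and 8.12 in the Mgp table, and the scale approaches log2 of scaled reads only for abundant genes. On this scale a doubling from 100 to 200 scaled reads in the Slpi table is a difference of 0.36, a doubling from 1000 to 2000 one of 0.77, and a doubling from 10000 to 20000 one of 0.97. Log2 differences below therefore understate the change of weakly expressed genes. Where a fold is given for a named gene within a table, it is the ratio of scaled reads, and other named genes have the log2 difference alone.

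The transform follows a closed form with the smallest value as its only constant, so it was inverted. Every value came out as a whole number of reads within a tolerance of 0.001 (100% of values), which gave read totals of 12.2 M to 28.5 M per library in the Slpi table and 12.1 M to 23.3 M in the Mgp table. The tables were normalized separately. Tests were made only within a table, and levels set across the tables are CPM, relative to each library's total, without a test. Distances across the tables used the recovered reads, scaled over all 20 libraries together, also without a test. Replicates of a hairpin differed by more than sampling noise, with a chi-square per degree of freedom of 1.54 to 7.55 over genes with at least 20 reads, so the replicates of a hairpin were not copies of each other; libraries of different hairpins were not compared in this way.

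Genes were tested when their mean lay at least 1 unit above the smallest value of the table, which left 9489 of 23480 genes in the Slpi table and 9174 in the Mgp table. This minimum corresponds to 121 scaled reads in the Slpi table and 139 in the Mgp table, a stricter bound than was anticipated when it was set. Mgp itself fell below it in its own table and was tested in a fit over all 19354 genes with any spread. The tests were limma's moderated tests with an intensity trend (limma 3.58.1, R 4.3.3) in a means model over the 5 hairpins of a table, two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p-values come from these fits or, for gene lists, from limma's camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The contrasts were the TRC hairpin minus the mean of the 4 shERWOOD hairpins, and each of the 10 pairs of hairpins per table. The designs, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

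Named genes were, per table, the 10 called genes with the largest positive and the 10 with the largest negative log2 difference for which both TRC libraries lay outside the range of the other 8, passing over gene models without a proper name. To these were added both targets, up to 4 called members of each list with the largest absolute differences, the 3 highest and 3 lowest called genes of the shERWOOD pair with the most calls, and the 5 higher and 5 lower genes with the largest smaller difference among those called the same way in both tables. A few genes that this rule picked are not reported here, although they stay in the counts. The 19 gene lists covered p53 targets, interferon-stimulated genes, the integrated stress response, endoplasmic reticulum chaperones, ribosomal proteins, the cell cycle, cholesterol synthesis, hypoxia and glycolysis, epithelial and mesenchymal genes, NF-kappaB and inflammation, BMP targets, the small RNA pathway, oxidative stress and drug efflux, immediate early genes, mitochondrial mRNAs, histones, and markers of immune and endothelial cells.

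The procedure was tested on simulated reads drawn from the real means and depths with 200 changed genes. In the Slpi table's simulation over 9508 genes, 86.6% of genes changed 1.25-fold, 100% of those changed 1.5-fold and 100% of those changed 2-fold were recovered, with 2.05% false calls. In the Mgp table's simulation over 9178 genes the shares were 92.5%, 98.5% and 98.5%, with 2.53% false calls. The spread assumed there was a single value for all genes, so real recovery can be lower. All hairpins shared 1 mean per gene apart from the changed genes. The median count among shERWOOD pairs was therefore 0, against 312.5 and 731.5 in the real Slpi and Mgp tables. The shares of false calls thus leave out differences between lines.

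Alternatives changed 1 choice at a time: no filter or a minimum of 3 units, equal library medians, quantile normalization, no intensity trend, a replicate block, limma's voom on the recovered reads, hairpin means as samples (1 TRC sample, with the spread of the 4 shERWOOD means), each library or shERWOOD hairpin left out, a difference of at least 1, and an adjusted p under 0.01. A voom fit over genes with a mean of at least 10 scaled reads, and refits of the Mgp level without the filter, were added after seeing the data. Gene positions, transcript lengths, GC content and 3′ UTR sequences came from GENCODE M21 on GRCm38, the assembly that mm10 denotes, with Python 3.11.15 and numpy 2.4.6. Symbols matched for 99.4% of tested genes in each table, 9007 directly and 428 through older symbols in the Slpi table, and 8713 and 409 in the Mgp table. Figures were drawn with matplotlib 3.10.9. The sequences of the hairpins are not given in the labels, and complementarity to them was not analysed here.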

Results

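The 10 hairpins studied in the mouse mammary carcinoma line 4T1 were profiled by RNA sequencing. The question was how far shRNAs from the TRC collection, and microRNA-embedded shRNAs picked by the shERWOOD algorithm, disturb genes other than their target. For Slpi, which encodes a secreted inhibitor of leukocyte serine proteases, there was 1 TRC hairpin (66708) and 4 shERWOOD hairpins (Slpi1U1, Slpi1U2, Slpi2 and Slpi4). For Mgp, which encodes matrix Gla protein, a secreted inhibitor of calcification, there was 1 TRC hairpin (88943) and 4 shERWOOD hairpins (Mgp1, Mgp1U1, Mgp1U3 and Mgp2). Each hairpin had 2 libraries, with 12.2 M to 28.5 M reads in the Slpi table and 12.1 M to 23.3 M in the Mgp table. Levels are given as CPM, the reads of a gene relative to all counted reads of the library.

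The target transcripts were higher in the TRC line than in the shERWOOD lines of the same table. Slpi lies on the minus strand of chromosome 2 (GRCm38, 164354070 to 164389095, ENSMUSG00000017002), with 4 exons in its main transcript. Mgp lies on the minus strand of chromosome 6 (136872435 to 136875823, ENSMUSG00000030218), also with 4 exons. Slpi stood at 151 ± 8.14 CPM in 66708 (SD, n = 2) and at 48.2 to 60.9 CPM in the 4 shERWOOD lines. This was a 3.01-fold difference in scaled reads and a log2 difference of 1.24 ± 0.04 (SE; limma, adjusted p = 9.408e-12). Among the shERWOOD hairpins, Slpi in Slpi4 was above Slpi1U1 (adjusted p = 0.0118) and above Slpi2 (adjusted p = 0.0130), and the other 4 pairs did not pass.

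Mgp stood at 15.8 ± 0.570 CPM in 88943 (SD, n = 2) and at 2.83 in Mgp1, 8.32 in Mgp1U1, 1.15 in Mgp1U3 and 1.99 in Mgp2. The log2 difference of 88943 was 0.70 ± 0.03 on the deposited scale (SE; limma, adjusted p = 9.882e-09) and 2.39 with voom on the recovered reads. Mgp1U1 kept more Mgp transcript than Mgp1 (limma, adjusted p = 3.254e-04), Mgp1U3 (1.037e-05) and Mgp2 (9.299e-05). Mgp1 was above Mgp1U3 (0.21, adjusted p = 0.0230), and the other 2 pairs did not pass. With hairpin means as samples, where the TRC hairpin is a single sample and the spread comes from the 4 shERWOOD means alone, the Mgp difference of 88943 did not pass (adjusted p = 0.147).

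Across the tables, each shERWOOD line held its own target below every shERWOOD line aimed at the other gene. The tables were normalized separately, so these levels were not tested against each other. Slpi averaged 53.3 ± 6.07 CPM in the 4 Slpi-directed shERWOOD lines (SD, n = 4) and 498 ± 61.3 in the 4 Mgp-directed ones, so the former stood at 10.7% of the latter. For the TRC lines, Slpi was 151 CPM in 66708 and 140 in 88943, so the line assigned to Slpi stood at 108% of the other. That 66708 is aimed at Slpi rests on the table its samples belong to, and its Slpi level was not below that of the other TRC line. Mgp averaged 3.57 ± 3.24 CPM in the Mgp-directed shERWOOD lines and 20.6 ± 6.70 in the Slpi-directed ones, 17.3% of that level. Without Mgp1U1, at 8.32 CPM against 15.4 in the lowest Slpi-directed line, the mean was 1.99 CPM and the share 9.66%. Between the TRC lines, Mgp was 15.8 CPM in 88943 and 105 in 66708, or 6.65-fold higher in the latter. No line without a hairpin was measured, so none of these ratios is a knockdown against untreated cells.

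**Figure D1:**
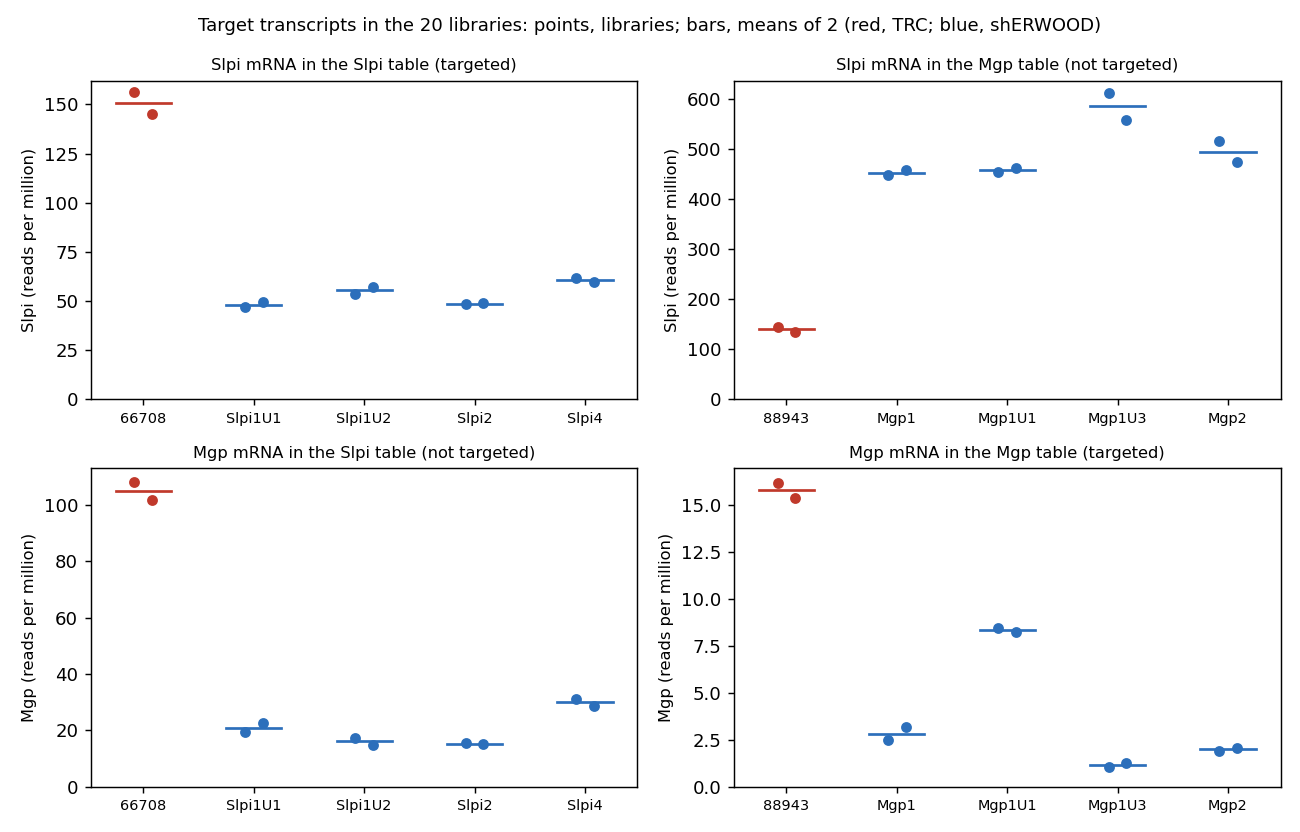
Reads per library total (CPM, vertical axes) of Slpi and Mgp in each of the 20 libraries by hairpin, in the table where the gene is the target and in the table where it is not. Points are libraries and bars are means of 2, and Slpi lies near 151 and 140 in the TRC lines, near 53.3 in the Slpi-directed and near 498 in the Mgp-directed shERWOOD lines.

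The first comparison asked whether 66708 gave another profile than the shERWOOD hairpins against Slpi. The genes below were the largest on the deposited scale, which compresses weakly expressed genes, so their order by fold differs. Mgp was 5.41-fold higher (log2 difference 1.64 ± 0.04, SE), and Mmp3, a secreted matrix metalloproteinase, 3.54-fold (1.47). Mmp9, a gelatinase, was 3.48-fold higher (1.10), and Sulf2, an extracellular heparan sulfatase, 4.41-fold (1.03). Slc5a3, a myo-inositol transporter on chromosome 16 (92058322 to 92087473), was 3.05-fold higher (1.53). S100a4, a calcium-binding protein linked to metastasis, was 2.69-fold higher (1.42). Ifitm3, a membrane protein that restricts viral entry, was 2.26-fold higher (1.07), and the integrin alpha subunits Itga8 and Itga1 were 3.44-fold (1.03) and 3.26-fold (0.97) higher. Lowest on that scale were Msln, the surface glycoprotein mesothelin on chromosome 17 (25748613 to 25754378), at 3.10-fold lower (−1.30), and Chac1, a glutathione-degrading enzyme, at 5.13-fold lower (−1.28).

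Asparagine synthetase, Asns, was also lower in 66708 (−0.90), mitochondrial alanine transaminase, Gpt2, was 3.14-fold lower (−0.91), and mitochondrial phosphoenolpyruvate carboxykinase, Pck2, 2.80-fold (−0.91). Plin2, a lipid droplet coat protein, was 2.17-fold lower (−0.96), Kank3, a cytoskeletal adaptor, 2.54-fold (−0.94), and B3gnt3, a glycosyltransferase, 2.07-fold (−0.84). The hypoxia-induced genes Car9, a carbonic anhydrase, and Ndrg1 were 2.36-fold (−0.92) and 1.97-fold (−0.87) lower. In all, 5285 of 9489 genes were called (limma, Benjamini-Hochberg), 3046 higher and 2239 lower in 66708. Both TRC libraries lay outside the range of the other 8 for 2560 called genes above and 1822 below. Of all tested genes 48.6% lay outside in this way for 66708, and 5.13% to 10.1% for each shERWOOD hairpin in turn, whose comparison range also holds the TRC libraries and is widened by them. Chance would give 4.44% if all libraries were alike, and 40.0% if all 5 hairpins differed alike and replicates did not. Few changes were large, as 11 called genes differed by at least 1 unit on the deposited scale, and 95 by at least 2-fold with voom. The share of calls that were higher was 57.6% as deposited and 48.3% with library medians set equal, and with hairpin means as samples 3042 genes were called. S100a4 shares 51.7% of its annotated exon bases with the overlapping model Gm42674, so its count is uncertain.

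By gene list, all 18 tested cholesterol synthesis genes were higher in 66708, among them the sterol demethylase gene Cyp51 (0.69) and the isomerase gene Idi1 (0.68). The list passed camera (adjusted p = 3.185e-11), and did so with adjusted p = 0.0181 with an estimated correlation. Of 16 genes of the integrated stress response, a program driven by the transcription factor ATF4, 11 were lower and 5 did not pass. Among the 11 were Chac1, Asns, the pseudokinase Trib3 (−0.82) and Aldh18a1, an enzyme of proline synthesis (−0.66). This list passed camera as well (adjusted p = 8.845e-08; adjusted p = 0.0181 with an estimated correlation). These genes also differed between the shERWOOD hairpins, with Chac1 at 1179 ± 653 scaled reads over their 4 means (SD). With hairpin means as samples Chac1 (adjusted p = 0.0510) and Trib3 (0.0823) no longer passed.

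Of 17 hypoxia and glycolysis genes 13 were lower and 1 higher in 66708. Among the lower ones were Car9, Ndrg1, the angiogenic growth factor Vegfa at 2.73-fold (−0.83) and Pdk1, a kinase that restrains pyruvate oxidation (−0.71). The list passed camera (adjusted p = 2.203e-07), but not with the other form of the test (adjusted p = 0.0618 with an estimated correlation). Of 15 endoplasmic reticulum chaperone genes 13 were higher and 1 lower, with Calr (0.62), Dnajc3 (0.56), Pdia6 (0.53) and Manf (0.47) among the higher ones. Their camera test gave adjusted p = 4.040e-04, and adjusted p = 0.0598 with an estimated correlation. All 5 tested BMP target genes were higher, among them the differentiation inhibitors Id3 (0.93), Id2 (0.47) and Id1 (0.43) and the inhibitory Smad7 (0.26). Camera gave adjusted p = 6.606e-04 for them, and adjusted p = 0.0598 with an estimated correlation.

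Of 13 interferon-stimulated genes 7 were lower in 66708, among them Oasl1 (−0.41) and the RNA sensor Ifih1 (−0.36), and 6 did not pass. Camera gave adjusted p = 0.00216, and adjusted p = 0.0598 with an estimated correlation. Of 36 ribosomal protein genes 23 were higher and 1 lower, with Rps14 at 0.46 and Rps9 at 0.36. Camera gave adjusted p = 6.914e-04, and adjusted p = 0.531 with an estimated correlation. Without replicate 1 of 66708 the ribosomal list did not pass camera (adjusted p = 0.0670), and pseudogene copies make single ribosomal protein counts uncertain. The ribosomal RNA precursor Rn45s took 2.77% and 2.31% of reads in the 66708 libraries and 1.27% to 1.87% in the shERWOOD libraries of this table. Adjusted over the list alone, the counts of the 7 lists above were the same, except 14 lower hypoxia genes and 24 higher ribosomal protein genes.

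The remaining lists did not pass camera in the Slpi table, although single members did. Among 13 p53 target genes 8 were higher, led by Perp, a desmosomal membrane protein (0.95), and 2 lower (adjusted p = 0.188). Of 24 cell cycle genes 6 were higher and 11 lower, with the replication helicase subunit Mcm2 at −0.67 and the kinetochore gene Cenpf at −0.50 (adjusted p = 0.0862). The cell cycle list passed under quantile normalization (adjusted p = 0.0121) and with a minimum of 3 units (0.0121), and without the filter the p53 (0.0424), epithelial (0.0171) and histone (0.0120) lists did. Of 12 epithelial genes 8 were higher and 3 lower, with the keratins Krt14 at 0.91 and Krt7 at −0.47 (adjusted p = 0.146). Of 12 mesenchymal genes 7 were higher and 3 lower, with Col6a1, a collagen chain, at 0.69 and Tnc, tenascin C, at −0.46 (adjusted p = 0.285). The NF-kappaB list had 2 higher and 5 lower of 14, with the chemokine Ccl2 at 0.84 (adjusted p = 0.285).

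The oxidative stress and efflux list had 8 higher and 6 lower of 18 in the Slpi table, with the cystine transporter Slc7a11 at −0.54 (adjusted p = 0.684). The immediate early list had 3 and 3 of 13, with the transcription factor gene Atf3 at −0.62 (adjusted p = 0.495). Of 13 small RNA pathway genes the nuclear transport GTPase gene Ran (0.38) and Xpo5, which exports microRNA precursors (0.11), were higher and the Argonaute gene Ago3 (−0.31) lower (adjusted p = 0.544). Xpo5 did not pass with equal library medians (adjusted p = 0.0659). Histone genes had 4 higher of 9 (adjusted p = 0.203). Counts adjusted over the list alone were the same, except 9 higher p53 targets, 7 higher and 12 lower cell cycle genes, and 1 higher histone gene.

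The second comparison asked the same of 88943 and the shERWOOD hairpins against Mgp. On the deposited scale the gene most raised in 88943 was Fgfbp1, a secreted carrier of fibroblast growth factors on chromosome 5 (43978858 to 43981779), at 4.48-fold (log2 difference 1.67 ± 0.03, SE). Slc4a11, a membrane ion transporter, followed at 10.3-fold (1.66), Chac1 at 7.57-fold (1.64), Pck2 at 5.85-fold (1.62) and Ddit4, a stress-induced inhibitor of mTOR signalling, at 6.53-fold (1.61). Gpt2 was 6.77-fold higher (1.58) and Nupr1, a stress-induced nuclear protein, 4.92-fold (1.52). Lama3, a laminin chain, was 5.38-fold higher (1.47), Car9 3.92-fold (1.43) and Slc7a11 3.86-fold (1.41). Lowest on that scale was Cck, the precursor of the peptide hormone cholecystokinin on chromosome 9 (121489824 to 121495694), at 11.4-fold lower (−1.95). Ptgs2, the inducible prostaglandin synthase, was 3.73-fold lower (−1.79) and Slpi 3.91-fold (−1.75).

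Prl2c2, a placental growth hormone of the prolactin family, was 22.3-fold lower in 88943 (−1.70), a count that near-identical copies of the gene make uncertain. Gpx1, a glutathione peroxidase, was 3.26-fold lower (−1.61), and Cyp1b1, an oxidizing enzyme of foreign compounds and steroids, 9.50-fold (−1.52). Serpine2, an extracellular protease inhibitor, was 3.08-fold lower (−1.48), and Pno1, a ribosome assembly factor, 4.26-fold (−1.44). Odc1, ornithine decarboxylase of polyamine synthesis, was 2.77-fold lower (−1.35), and Mapk6, an atypical MAP kinase, 2.58-fold (−1.31). In all, 6490 of 9174 genes were called (limma, Benjamini-Hochberg), 2635 higher and 3855 lower in 88943. Both TRC libraries of 88943 lay outside the range of the other 8 for 2184 called genes above and 3267 below. Of all tested genes 60.4% lay outside for 88943, and 6.33% to 16.4% for each shERWOOD hairpin in turn, with the same widened range and the same chance shares of 4.44% and 40.0%. Of the called genes, 45 differed by at least 1 unit, and with voom 223 differed by at least 2-fold. Of the calls, 40.6% were higher as deposited and 50.3% with library medians set equal, and with hairpin means as samples 4151 genes were called.

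By gene list, 14 of 15 integrated stress response genes were higher in 88943, led by Chac1, Ddit4, Nupr1 and Slc7a11, and 1 did not pass. Camera gave adjusted p = 8.987e-11, and adjusted p = 0.0116 with an estimated correlation. Of 12 epithelial genes 10 were higher, with the adhesion molecule Epcam at 1.13, the tight junction gene Cldn4 at 0.84, and the keratins Krt19 at 0.65 and Krt7 at 0.62. The epithelial list passed camera (adjusted p = 2.192e-05; adjusted p = 0.0345 with an estimated correlation). Of 15 NF-kappaB and inflammatory genes 11 were lower and 2 higher. Among the lower ones were Ptgs2, the chemokines Cxcl5 (−1.27) and Ccl2 (−1.18), and Lcn2, an iron-sequestering secreted protein that was 32.1-fold lower, more than any other named gene by fold (−0.97). The Lcn2 fold rests on few reads, at 0.412 ± 0.146 CPM in 88943 (SD, n = 2). In the shERWOOD lines Lcn2 ranged from 6.53 CPM in Mgp1U1 to 21.3 in Mgp1U3. Camera for the NF-kappaB list gave adjusted p = 0.00175, and adjusted p = 0.0591 with an estimated correlation.

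Of 25 cell cycle genes 17 were lower and 1 higher in 88943. The ribonucleotide reductase subunit Rrm2 was at −0.77, the cyclins Ccnb1 at −0.52 and Ccne2 at −0.50, and Cdk1 at −0.47. The cell cycle list passed camera (adjusted p = 0.00321; adjusted p = 0.0591 with an estimated correlation), but not under quantile normalization (0.0742) or with a minimum of 3 units (0.770). Of 16 hypoxia and glycolysis genes 8 were higher and 4 lower, with Car9 at 1.43, Ndrg1 at 0.98 and Vegfa at 0.71, while the glycolytic enzyme gene Ldha was at −0.50. Camera gave adjusted p = 0.0138, and adjusted p = 0.132 with an estimated correlation, and with a minimum of 3 units the list did not pass (0.105). Histone genes had 6 of 9 higher (camera adjusted p = 0.0383; adjusted p = 0.612 with an estimated correlation). That call ended without replicate 1 of 88943 (adjusted p = 0.278), without replicate 2 of Mgp1U3 (0.0552) and with voom (0.0701). The histone call also ended without the filter (0.126), with equal library medians (0.0503) and under quantile normalization (0.0928). With voom over genes with a mean of at least 10 scaled reads it ended too (0.118). The BMP target list had 4 of 5 lower, with Id2 at −0.82 and Id3 at −0.47, and did not pass camera (adjusted p = 0.116). Adjusted over the list alone, the counts of these 7 lists were the same.

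Members of the other lists moved both ways in the Mgp table, and none of these lists passed camera. Of 11 p53 targets 3 were higher and 6 lower, with Gadd45a, a stress-induced growth arrest gene, at 1.33 and the nuclease gene Aen at −0.67 (adjusted p = 0.615). Of 15 endoplasmic reticulum chaperone genes 4 were higher and 10 lower, with Herpud1 at 1.01 and Dnajc3 at −0.46 (adjusted p = 0.615). Cholesterol synthesis had 7 higher and 5 lower of 18, with Idi1 at −0.60 and Mvd at 0.38 (adjusted p = 0.615). The small RNA pathway had 3 and 7 of 13, with Ran at −0.62 and Xpo5 at −0.51 (adjusted p = 0.615). Oxidative stress and efflux had 5 and 11 of 18, with the thioredoxin reductase gene Txnrd1 at −0.65 (adjusted p = 0.584).

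Immediate early genes had 5 higher and 6 lower of 13 in the Mgp table, with Ier3 at −0.61 and the AP-1 subunit gene Fosl1 at −0.58 (adjusted p = 0.829). Fosl1 shares 57.2% of its exon bases with Ccdc85b on the other strand, so its count is uncertain. Interferon-stimulated genes had 3 and 3 of 10, with Oasl1 at −0.42 and Stat2 at 0.37 (adjusted p = 0.754). Ribosomal proteins had 10 and 9 of 36, with Rps20 at 0.35 and Rps14 at −0.32 (adjusted p = 0.807, or 0.0149 under quantile normalization). Mesenchymal genes had 4 and 4 of 11, with Tnc at −0.99 and the fibronectin gene Fn1 at 0.43 (adjusted p = 0.913). Counts adjusted over the list alone were the same, except 4 lower cholesterol genes, 12 lower oxidative stress genes and 9 higher ribosomal protein genes. The median and the direction of camera differed in sign for the ribosomal and mesenchymal lists, and for the oxidative stress list in the Slpi table. The median and the mean differed in sign for the interferon list.

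Of 15 measured immune cell markers 2 exceeded 1 CPM, the lipopolysaccharide co-receptor gene Cd14 and Cd68. Cd14 stood at 14.5 CPM in 66708 and 12.5 in the shERWOOD lines of the Slpi table, and at 12.1 in 88943 and 13.0 in the shERWOOD lines of the Mgp table. Cd68, a lysosomal glycoprotein of macrophages below the filter, stood at 3.66, 6.60, 7.23 and 4.43 CPM in the same order and was not tested. Cd14 was the only immune marker tested, higher in 66708 by 0.14 (limma, adjusted p = 0.00620) and lower in 88943 at −0.09 (adjusted p = 0.0399). Both calls ended with hairpin means as samples (adjusted p = 0.0790 and 0.353). Of 12 endothelial markers 3 exceeded 1 CPM (Eng, Flt1 and Tie1) and 2 were tested. Eng, a TGF-beta co-receptor, stood at 40.2 CPM in 66708, 43.0 in the shERWOOD lines of that table, 41.5 in 88943 and 38.4 in the shERWOOD lines against Mgp. Flt1, a VEGF receptor, stood at 46.0, 41.3, 43.2 and 42.2 CPM in the same order, and Tie1 at 1.47, 4.51, 3.07 and 4.19. Flt1 was called in the Slpi table (0.16, limma, adjusted p = 0.00110), and in the Mgp table it was at −0.06 and did not pass (adjusted p = 0.168). None of the 13 mitochondrially encoded mRNAs was listed in the tables, so that sign of RNA quality was not analysed here.

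**Figure D2:**
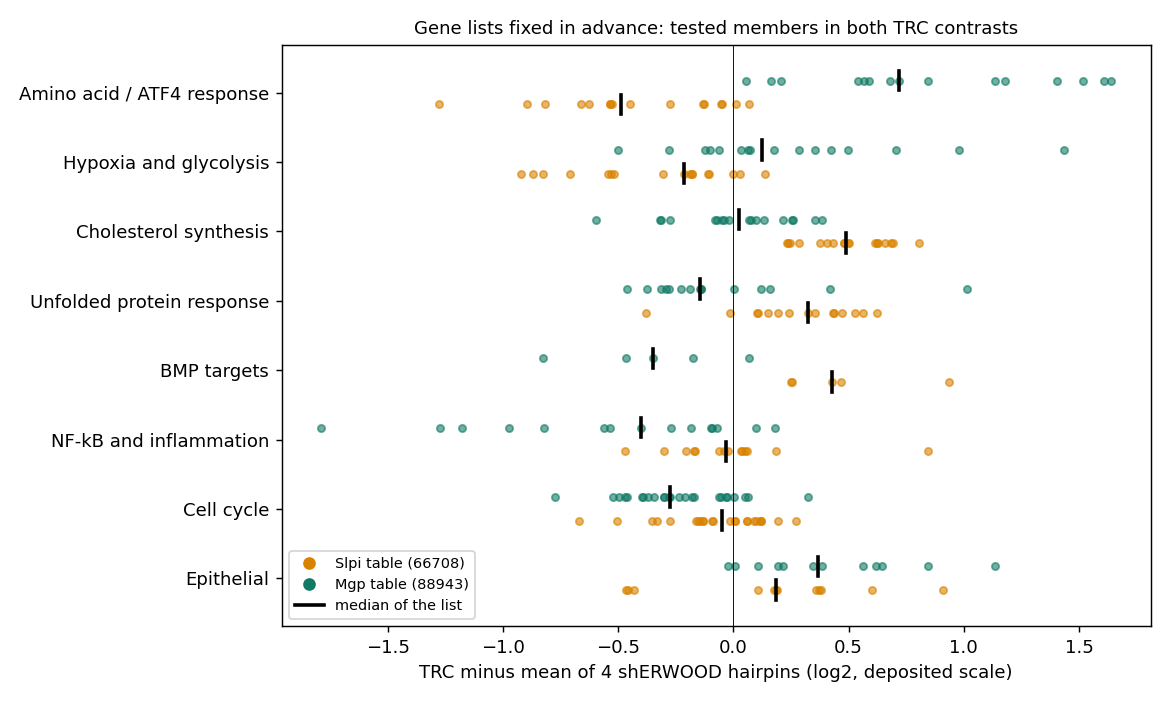
Log2 differences on the deposited scale (horizontal axis) of the tested members of 8 gene lists, TRC hairpin minus the mean of 4 shERWOOD hairpins, in the Slpi table (orange) and the Mgp table (green). Points are genes and black bars are medians, and the integrated stress response list has a median of −0.49 in the Slpi table and 0.72 in the Mgp table.

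Pair by pair, every pair with a TRC hairpin held more called genes than every pair without one in the same table. In the Slpi table the 4 pairs with 66708 had a median of 4553.5 called genes (3656 to 4602) and the 6 pairs among shERWOOD hairpins 312.5 (75 to 615). In the Mgp table the 4 pairs with 88943 had a median of 5868 (5806 to 6175) and the 6 others 731.5 (664 to 2307). Pearson's r across genes, which are not independent replicates, was 0.978 to 0.988 between 66708 and the shERWOOD hairpins. It was 0.993 to 0.997 among these and 0.997 to 0.998 between replicates. The Mgp values were 0.964 to 0.971 with 88943, 0.989 to 0.997 among shERWOOD hairpins and 0.996 to 0.999 between replicates.

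**Figure D3:**
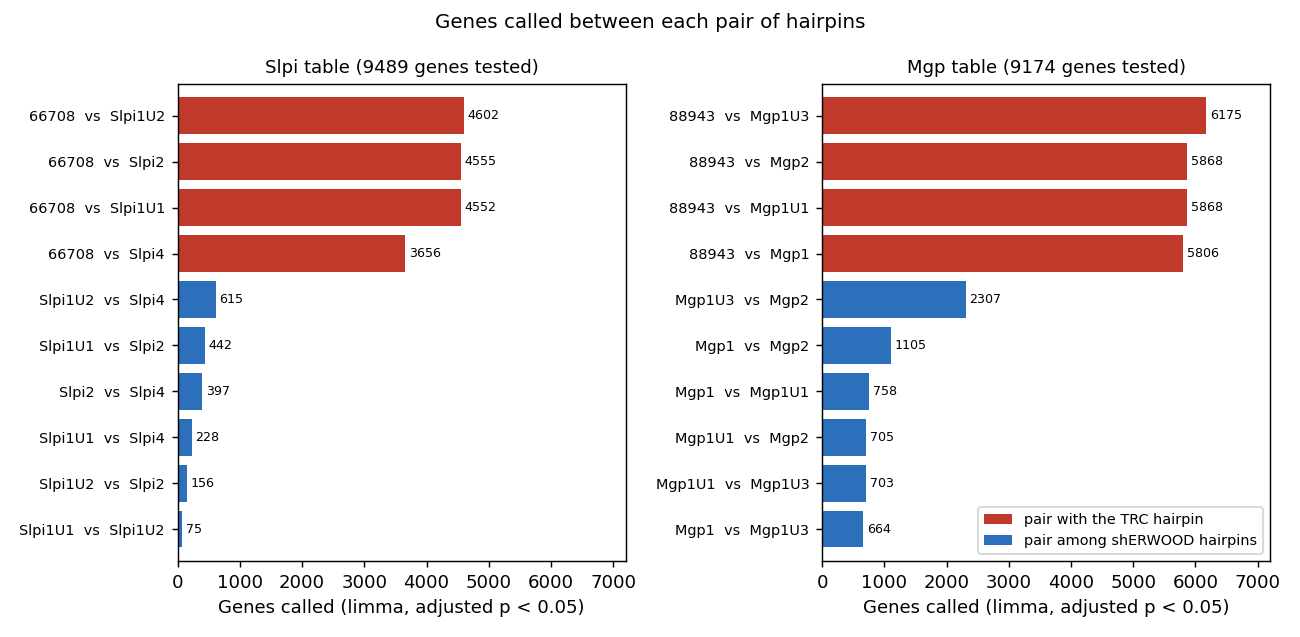
Number of genes called between each pair of hairpins (horizontal axis, limma, adjusted p under 0.05) in the Slpi and the Mgp table, with pairs that hold the TRC hairpin in red and pairs among shERWOOD hairpins in blue. The 4 red bars span 3656 to 4602 and 5806 to 6175 genes, the 6 blue bars 75 to 615 and 664 to 2307.

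The shERWOOD hairpins also differed from each other. Between Slpi1U2 and Slpi4, the pair with the most calls in the Slpi table, the long noncoding RNAs Kcnq1ot1 (log2 difference 1.05 ± 0.04, SE) and Neat1 (0.83 ± 0.05) were higher in Slpi1U2. So was Neb, the giant muscle protein nebulin (0.47 ± 0.04), while Mmp3 (−0.76), Ccl2 (−0.60) and the mitotic kinase Nek2 (−0.57) were lower (limma, largest adjusted p of these genes 2.072e-05). Between Mgp1U3 and Mgp2 the neutrophil chemokines Cxcl5 (1.31 ± 0.04) and Cxcl1 (0.79 ± 0.05) and Mmp3 (0.80 ± 0.05) were higher in Mgp1U3. The RNA-binding protein gene Rbmx (−0.70), D4Wsu53e (−0.60) and Kctd11 (−0.58) were lower there (limma, largest adjusted p of these genes 4.779e-04). Rn45s took 2.39% of reads in replicate 1 of Mgp2 and 1.29% in replicate 2. Counts among shERWOOD hairpins depended on single libraries, as without replicate 1 of Slpi2 the Slpi median fell from 312.5 to 128.5, and without replicate 2 of Mgp2 the Mgp median rose from 731.5 to 1759.

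The last comparison set the TRC contrasts of both tables against each other, over 9144 genes tested in both. By the smaller of both differences, the genes highest in both TRC lines were Mmp9 (1.10 and 1.34), Scd2, a fatty acid desaturase (0.73 and 0.78), Clu, a secreted chaperone (0.72 and 0.97), Jup, the junction protein plakoglobin (0.66 and 0.95), and Epcam (0.60 and 1.13). Lowest in both were Sorbs2, a cytoskeletal adaptor (−0.63 and −1.04), Rnf11, a RING finger protein (−0.53 and −1.06), and Prickle1, a planar polarity protein (−0.75 and −0.53). Next came Nabp1, a single-strand DNA-binding protein (−0.57 and −0.49), and Ptpn22, a tyrosine phosphatase (−0.48 and −0.58). Altogether 1129 genes were called the same way, 589 higher and 540 lower, where independent lists would share 864 and 877. Fisher's exact test gave a deficit in both directions (two-sided p = 2.337e-43, odds ratio 0.49, and p = 2.175e-67, odds ratio 0.40). Opposite calls were 2652, of which 1682 were higher in 66708 and lower in 88943 and 970 the reverse, against 1862 for independent lists. The uneven split depended on the scaling. In the same order it was 1243 and 1344 with library medians set equal, 1180 and 1264 under quantile normalization, and 1318 and 1325 with voom. Across genes r was −0.28 and Spearman's rho −0.29. The tables share no library, so the TRC contrasts share no control, and genes are not independent of each other, so these p-values overstate the evidence. Without replicate 1 of 66708, 745 genes were called the same way.

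**Figure D4:**
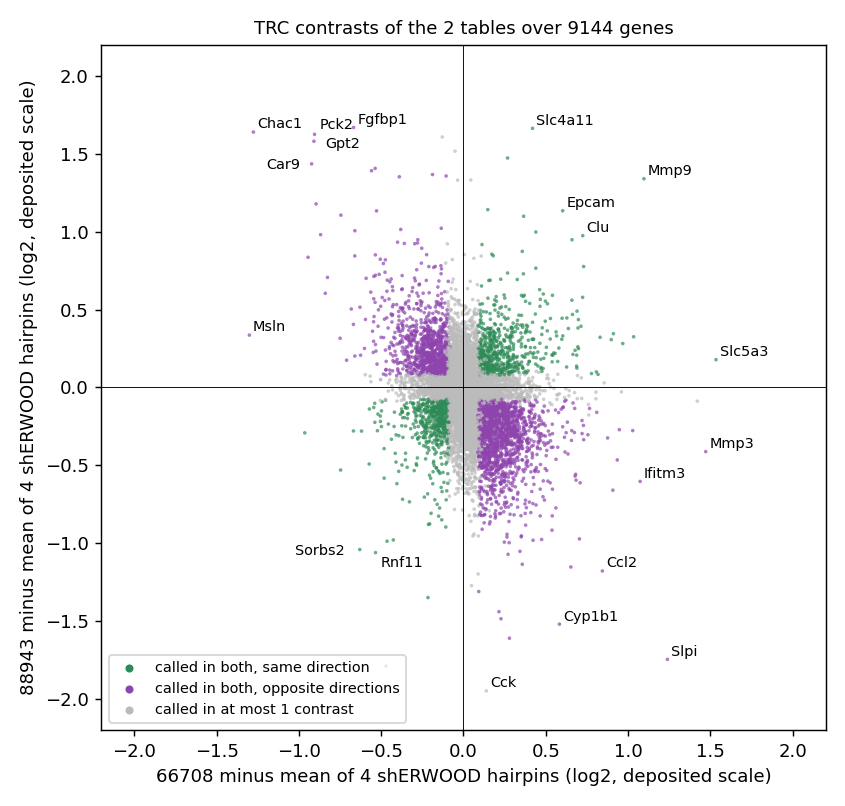
Log2 difference of each of 9144 genes between the TRC hairpin and the mean of 4 shERWOOD hairpins in the Slpi table (horizontal axis) and the Mgp table (vertical axis), on the deposited scale. Green points are the 1129 genes called the same way in both tables, purple points the 2652 called in opposite directions.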

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

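The tests of a shared drug and vector effect and of an exchange of lines were chosen only after the result was seen. The named genes below stood out because both libraries of 66708 lay on one side of all 8 shERWOOD libraries of their table, and both libraries of 88943 on the opposite side of theirs. The difference between the tables was not tested for any of these genes. Pairs of values below are log2 differences, TRC minus shERWOOD, in the Slpi table and then in the Mgp table. Over all 9144 genes tested in both tables, 2056 (22.5%) were apart from the shERWOOD libraries in this opposite way, 1313 higher in 66708 and lower in 88943 and 743 the reverse, and 793 were so in the same direction. These counts are on the deposited values and were not run under other scalings. The split of opposite calls, 1682 and 970 as deposited, was 1243 and 1344 with library medians set equal.

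Lower in 66708 and higher in 88943 were Chac1 (−1.28 and 1.64), Pck2 (−0.91 and 1.62), Gpt2 (−0.91 and 1.58), Asns (−0.90 and 1.18), Slc7a11 (−0.54 and 1.41), Aldh18a1 (−0.66 and 0.84), Atf3 (−0.62 and 0.21) and Osgin1 (−0.32 and 0.34). Of the hypoxia list, which had 8 higher and 4 lower of 16 in the Mgp table, the same held for Car9 (−0.92 and 1.43), Ndrg1 (−0.87 and 0.98), Vegfa (−0.83 and 0.71) and Pdk1 (−0.71 and 0.17). Of the epithelial list, which had 8 higher and 3 lower of 12 in the Slpi table, it held for the keratins Krt7 (−0.47 and 0.62) and Krt19 (−0.43 and 0.65), and beyond these lists for the growth factor carrier Fgfbp1 (−0.67 and 1.67), the surface glycoprotein Msln (−1.30 and 0.34), and Kank3 (−0.94 and 0.84), B3gnt3 (−0.84 and 0.60), Mki67 (−0.35 and 0.32), Col5a1 (−0.31 and 0.34) and Stat2 (−0.20 and 0.37).

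Higher in 66708 and lower in 88943, each against its own shERWOOD lines, were the target Slpi (1.24 and −1.75), and Ccl2 (0.84 and −1.18), Mmp3 (1.47 and −0.41), Serpine2 (0.23 and −1.48), Sulf2 (1.03 and −0.28) and Ctgf (0.63 and −0.22). Slpi itself was 151 CPM in 66708 and 140 in 88943. Its opposite signs went with the shERWOOD lines, at 53.3 CPM where Slpi was the target and 498 where it was not. The BMP-induced genes Id3 (0.93 and −0.47), Id2 (0.47 and −0.82), Id1 (0.43 and −0.35) and Runx2 (0.25 and −0.17) shared this direction, as did the chaperone genes Dnajc3 (0.56 and −0.46), Calr (0.62 and −0.29), Manf (0.47 and −0.32) and Hyou1 (0.36 and −0.37). Of the cholesterol synthesis list, which had 7 higher and 5 lower of 18 in the Mgp table, it held for Idi1 (0.68 and −0.60) and Hmgcs1 (0.61 and −0.32). Further genes of this direction were Cyp1b1 (0.58 and −1.52), Gpx1 (0.28 and −1.61), Pgd (0.42 and −0.42), Txnrd1 (0.11 and −0.65) and Gclc (0.19 and −0.48). The others were Ifitm3 (1.07 and −0.60), Mapk6 (0.0929 and −1.31), Ran (0.38 and −0.62), Plk2 (0.37 and −0.58), Aen (0.23 and −0.67), Ier3 (0.22 and −0.61), Cdk1 (0.20 and −0.47), Xpo5 (0.11 and −0.51) and Dusp6 (0.29 and −0.22). Ctgf shares 23.2% of its exon bases with a transcript on the other strand. Xpo5 in the Slpi table and Runx2 in the Mgp table did not pass under quantile normalization (adjusted p = 0.148 and 0.198).

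For the opposite run of the TRC contrasts, an effect of puromycin and the TRC vector shared by both lines was considered. As the main source of both contrasts it would give more genes called the same way than independent lists. There were 1129, where independent lists would give 1741. That count is the opposite run itself, so it is not separate evidence. A smaller shared effect was not excluded. Each contrast has its own shERWOOD set, and these sets stood 0.29 to 0.38 apart in root mean square log2 distance. Opposite signs can therefore come from the shERWOOD lines as well as from the TRC lines. An exchange of the TRC lines between the tables, with hairpins that lower their targets, was argued against by Mgp, which stood at 5.09 times the shERWOOD mean of the Slpi table in 66708 and was 6.65-fold higher there than in 88943. Other values went the way of an exchange: Slpi in 88943 stood at 0.281 of the shERWOOD mean of the Mgp table, and on average each TRC line lay nearer to the shERWOOD lines of the other table. A cell state that varies between lines of a single source could not be excluded: the first component of the 4 shERWOOD hairpins had an absolute r across genes of 0.0160 with this axis in the Slpi table and 0.164 in the Mgp table, and 4 hairpins per table are too few to decide. The sequence of each hairpin, the vector, the drug and the history of each line cannot be told apart here, with 1 TRC hairpin per gene, and the depletion of the targets stays among the open biological explanations, untested.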

How the results depend on the processing

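Voom over genes with a mean of at least 10 scaled reads and the refits of the Mgp level over all genes, without the filter, were chosen after seeing the data. No named gene and no camera test of a list changed direction under the alternatives run for it. The calls of the TRC contrasts turned from mostly higher to mostly lower in the Slpi table (57.6% to 48.3% higher), and the reverse in the Mgp table (40.6% to 50.3%), with equal medians. With voom the median changed sign for the oxidative stress list of the Slpi table (0.01 to −0.02) and the ribosomal list of the Mgp table (−0.04 to 0.03), neither of which passed. Of 3966 values of named genes under alternatives, 3904 stayed on their side of the threshold, 61 no longer passed and 1 newly passed, and of 568 list values 549, 12 and 7. The low histone genes and Cd14 made up many of these. Equal medians, quantile normalization, no intensity trend and voom kept the counts within 1.5 times, as did leaving out any shERWOOD hairpin for the TRC contrasts and the shared genes, while the counts of pairs were not run without a hairpin. The cause was not tested unless stated.

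Without the filter the median count of pairs among shERWOOD hairpins was 135 (Slpi) and 386 (Mgp). With a minimum of 3 units, which leaves 2719 and 2488 genes to test, the TRC contrasts had 1735 and 1928 calls, pairs with the TRC hairpin 1544 and 1812.5, pairs among shERWOOD hairpins 139.5 and 262.5, and 355 genes were called the same way in both. With hairpin means as samples, which leaves 1 TRC sample and the spread of 4 shERWOOD means, the counts were 3042, 4151 and 352 shared, and the Mgp level was 0.70 and did not pass (adjusted p = 0.147). At a difference of at least 1 they were 11 and 45, for pairs with the TRC hairpin 14.5 and 49.5, for pairs among shERWOOD hairpins 0.5 and 0, with 1 shared gene; the compressed scale lowers these counts. At an adjusted p under 0.01 pairs among shERWOOD hairpins had 131 and 244 calls and 711 genes were shared.

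Leaving out each library in turn, where a lone library is assumed to vary like the others, gave 3742 to 5429 calls in the Slpi contrast and 5461 to 6799 in the Mgp contrast, 3297 to 4477.5 and 4912 to 6269 for pairs with the TRC hairpin, 128.5 to 572 and 295 to 1759 for pairs among shERWOOD hairpins, 745 to 1205 shared genes, a Slpi level of 1.19 to 1.29 and a Mgp level of 0.68 to 0.72. The median among shERWOOD hairpins moved by over 1.5 times without Slpi1U1 replicate 1 (199) or 2 (572), Slpi2 replicate 1 (128.5) or 2 (157), Slpi4 replicate 1 (135.5) or 2 (132.5), Mgp1 replicate 1 (295) or 2 (301.5), Mgp1U1 replicate 1 (344) or 2 (340.5), and Mgp2 replicate 1 (1344) or 2 (1759). The shared count did so without replicate 1 of 66708 (745).

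The replicate number did not pair libraries in a uniform way, as r of the number deviations between hairpins was −0.53 to 0.55 in the Slpi table and −0.17 to 0.28 in the Mgp table. It exceeded 0.1 in 3 of 10 pairs of hairpins in the Slpi table and 4 of 10 in the Mgp table. Values this far from 0, of either sign, mean that the replicate differences of some hairpins ran along a common direction across genes. With 1 difference per hairpin, they do not show that libraries of different hairpins were handled together. The source of that direction, such as a batch, was not tested. With the number as a replicate block there were 5199 and 6595 calls, with a median of 248 and 997 among shERWOOD hairpins, and of the named genes and lists the block ended 1 call, that of Hist1h4d (adjusted p = 0.0503). Averaging 4 libraries per hairpin and a correlation between libraries of a letter were not run, since each table holds 2 columns per hairpin. A count of 3 reads corresponded to 0.105 to 0.248 CPM, counting error only.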

Other observations

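The tests of gene lists between pairs of shERWOOD hairpins and the comparison of levels across tables were chosen only after the result was seen. The shERWOOD lines against Slpi differed among themselves in the ATF4-driven stress response. Chac1, which degrades glutathione, stood at 23.2 ± 2.27 CPM in Slpi1U1 (SD, n = 2), 87.6 in Slpi1U2, 116 ± 5.06 in Slpi2 and 60.3 in Slpi4, and at 13.2 in 66708. Asparagine synthetase, Asns, followed with 190 in Slpi1U1, 247 in Slpi1U2, 339 in Slpi2 and 222 in Slpi4. Of the 16 genes tested, 14 were lower in Slpi1U1 than in Slpi2 with a median log2 difference of −0.68 (camera adjusted p = 1.548e-38 over 96 list and pair tests; adjusted p = 0.00216 with an estimated correlation). Between Slpi1U1 and Slpi1U2, 13 were lower in Slpi1U1, with a median of −0.32 (adjusted p = 5.726e-36; adjusted p = 0.00216 with an estimated correlation). Between Slpi1U2 and Slpi4, 3 were higher in Slpi1U2 (adjusted p = 0.158 with an estimated correlation).

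Among the shERWOOD lines against Mgp, inflammatory genes were highest in Mgp1U3. The neutrophil chemokine Cxcl5 stood at 90.2 ± 0.147 CPM in Mgp1U3 (SD, n = 2), 34.6 in Mgp1, 23.8 in Mgp1U1 and 22.6 in Mgp2, and the monocyte chemokine Ccl2 at 65.8, 31.3, 34.0 and 29.7. Of 15 NF-kappaB genes, 6 were higher in Mgp1U3 than in Mgp1 (camera adjusted p = 1.987e-10; adjusted p = 0.0355 with an estimated correlation) and 7 than in Mgp2 (adjusted p = 1.131e-07; adjusted p = 0.0402 with an estimated correlation). Cholesterol synthesis genes were higher in Mgp1 than in Mgp1U1 for 14 of 18 (adjusted p = 1.741e-14; adjusted p = 0.0355 with an estimated correlation).

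Across the tables, root mean square log2 distances were taken from recovered reads scaled over all 20 libraries together, without a test. The distance of 66708 was 0.26 to 0.32 to the Mgp-directed shERWOOD lines (mean 0.28) and 0.27 to 0.34 to the Slpi-directed ones (mean 0.32). These ranges overlapped. The distance of 88943 was 0.28 to 0.31 to the Slpi-directed (mean 0.29) and 0.43 to 0.48 to the Mgp-directed shERWOOD lines (mean 0.45). Chac1 was 13.2 CPM in 66708 and 10.4 in the Mgp-directed shERWOOD lines, and 86.2 in 88943 and 71.8 in the Slpi-directed ones. Car9, the hypoxia-induced carbonic anhydrase, was 46.5 and 35.9, and 154 and 116, in the same order. Trib3, Asns, Vegfa, Ccl2 and Msln also lay nearer to the shERWOOD mean of the other table in both TRC lines. Cxcl5 and Lcn2 did not in 66708. Cxcl5 was 11.3 CPM there, 11.2 in the Slpi-directed and 42.8 in the Mgp-directed shERWOOD lines. Lcn2 was 2.08 there, 4.73 in the Slpi-directed lines and 6.53 or more in each Mgp-directed one. Cyp1b1 in 66708, at 28.6, lay between 13.7 and 52.4 in the same sets. Distances among shERWOOD lines against the same gene were 0.12 to 0.16 for Slpi and 0.15 to 0.20 for Mgp, and between these sets 0.29 to 0.38.

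The TRC hairpin of each table stood apart from the other 4. Of the 25 ways to pick a hairpin per table, 1, the real one, reached its sum of 11775 calls, with 8787 the highest of the others. That share of 0.04 is the lowest this test can give, so chance in the choice of hairpin was not excluded. With 1 TRC line per table, a line apart for any other reason would give the same result. A GC content and transcript length trend as the whole cause was argued against, since after its removal 5363 genes were called in the Slpi contrast, 5250 before, and 6570 in the Mgp contrast, 6451 before. A seed, the part of a small RNA that pairs with 3′ UTR sites, stays open for both TRC hairpins: the share of mRNAs whose strongest lowering 7-mer was at least as strong as the target's was 0.329 for 66708 and 0.0554 for 88943. In simulations with a planted shift of −0.20 for seed sites, the planted 7-mer was the strongest in 20 of 20 runs for each target, but the share was under 0.05 in 6 runs for Slpi and 9 for Mgp, and in 1 of 20 runs without a planted shift for each, so this test could miss such an effect. The planted shift was larger than those of the strongest target 7-mers, −0.04 for Slpi and −0.07 for Mgp. Shifts of that size were not simulated.

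Genes with the 7-mer TACTGAA in their 3′ UTR were lower in 88943, a 7-mer at nucleotides 466 to 472 of the Mgp mRNA and the strongest lowering one of all 15945 scored (1135 genes, mean shift −0.07 ± 0.01 SE). Of the 7-mers scored, 3.69% lie in the Mgp mRNA, so the strongest could fall there by chance. A 3′ UTR composition trend shared with the 66708 contrast was argued against, as 77.3% of 7-mers had at least as large an absolute z there, and with the 66708 contrast as a covariate the rank of TACTGAA stayed 1. Pairing beyond the 7-mer stayed open: the 596 genes with a flanking base of the Mgp site differed from the 539 others by a log2 difference of −0.0430 ± 0.0258 (SE). A seed of 88943 that matches this site may contribute a small part of the contrast, a hypothesis found and tested on the same data. The share of 0.0554 did not pass, but it could not have been lower. Of the 396 mRNAs compared, 21 also hold TACTGAA, the strongest 7-mer of all scored, and so count as equally strong. The share therefore decides nothing about this seed. The sequence of 88943 is not given in the labels and would decide it.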
